A study of Sus scrofa with 6 samples.

How the data were processed

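Lymph node, spleen and thymus were sampled from RAG2 biallelic knockout pigs and their wild-type littermates at 3 months of age, per the labels, giving 6 libraries. Per the labels' protocols, total RNA was extracted with a silica column kit (RNeasy) and libraries were made with a stranded total RNA kit (TruSeq). Per the submitters' processing notes, the tools FastQC 0.11.9, Trimmomatic 0.39, STAR 2.7.9a and Cufflinks 2.2.1 and the genome build Sscrofa11.1 were used. The notes give neither their order nor their settings, and the gene annotation, the strand setting and the treatment of fragments shared by several genes are not given in the sources used here. Genes with near-identical copies or overlapping neighbours are therefore uncertain.

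For each tissue 1 table of FPKM values and 1 table of counts was used, both with 4122 genes. FPKM values (fragments normalised to transcript length and sequencing depth) were deposited by the authors, calculated separately in each tissue table. The deposited count tables hold estimated counts of fragments that the authors had multiplied by 1 factor per library. This was read from the values, of which 97.0 to 99.2% were whole numbers within 0.02 after division by the most frequent value above 0, a step between 0.925 and 1.08. Each count was divided by this step and rounded to whole fragments. The tables hold part of the genes, so the totals of 1922553 to 2541727 fragments are those assigned to listed genes and not the depth of the libraries. The 10 genes with the most fragments took 14.5 to 17.0% of them in each library. The most abundant gene was EEF1A1 in each library except the knockout spleen, where it was FTL.

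Gene symbols were used as the tables give them. Of these, 3721 matched a current symbol of the reference annotation for Sscrofa11.1, 225 matched through an older name and 176 had no match. Members of the gene lists were searched under older names as well, which found 22 of them, for example NKL for the human GNLY, RAG-1 for RAG1, IL8 for CXCL8, TOPOII for TOP2A and GCET2 for GCSAM. Coordinates come from the same annotation and are counted from 1.

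Within each tissue, genes with at least 1 FPKM in at least 1 of the 2 libraries were taken as measured. The size of a difference is the log2 ratio of knockout over wild type after adding 1 FPKM to each, and a gene was called at an absolute value of at least 1. No test across genes was made and no p-value is given, since each tissue and genotype holds 1 library; a fit of the genotype across tissues, paired within tissue, was not made. Beside each call stands a 95% Clopper-Pearson interval of the ratio of fragment counts, scaled by the factor per library that the deposited counts carry. For a gene at 0 fragments in a library the fold is a lower bound against 3 fragments per library. Genes with 10 or more fragments in both libraries had FPKM per fragment that differed 2-fold or more between the libraries in 4 of 2465 cases in lymph node, 5 of 2470 in spleen and 3 of 2420 in thymus. Calls on fewer than 10 fragments in both libraries numbered 117, 91 and 146.

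The main tests, 33 gene lists for cell types and pathways, 7 gene families and the rule for named genes were fixed before the data were examined. The named genes are RAG1 and RAG2 in every tissue, up to 3 members past the size threshold with the largest absolute log2 ratio for each list and tissue, and the 5 highest and 5 lowest genes with a symbol and at least 5 FPKM in 1 library of each tissue. Values of a gene named in a tissue may be given in the others, and lists with fewer than 3 called members may go without names. Some genes that the rule named are not reported here. Lists share members, among them KIT, NFE2, RAG-1 and POU2AF1. A list's median was placed among 10000 random lists of the same size, matched on mean expression in 20 bins.

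The calculations were tested on simulated counts drawn from the values of the wild-type libraries and the totals of both genotypes, with 200 genes changed. Genes seen mainly in the knockout were thus simulated near the floor, and the rates below do not describe them. By size threshold and counting interval together, 97.0, 96.0 and 97.0% of genes made 4-fold higher were recovered in lymph node, spleen and thymus, 96.0, 92.0 and 82.0% of those made 4-fold lower, and 40.0, 44.0 and 40.0% of those made 2-fold higher. Unchanged genes were called in 0.258, 0.227 and 0.222% of cases with the interval and in 2.25, 2.00 and 2.33% without it. The simulated noise is counting error alone.

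Alternatives were the deposited counts scaled to their total, with edgeR's TMM factors or with DESeq2's size factors, pseudocounts of 0.1 and 5, no expression minimum, a minimum of 5 FPKM, centring on the median, a threshold of 2 and the counting interval. A minimum of 10 fragments, and the counting interval applied to comparisons between tissues, were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 were used.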

Results

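RNA sequencing of lymph node, spleen and thymus compared pigs carrying a biallelic RAG2 knockout with wild-type littermates at 3 months of age. RAG2 and its partner RAG1 form the recombinase that assembles antigen receptor genes in developing T and B cells, and the series title speaks of immunodeficient pigs with the deletion of a single amino acid. There was 1 library per tissue and genotype, 6 in all, so no difference within a tissue has a replicate check. The tables list 4122 genes, part of the genes of the pig. Fragments assigned to them numbered 1922553 in the wild-type and 2021583 in the knockout lymph node. They numbered 2084770 and 2514982 in spleen, and 2541727 and 2397921 in thymus. Values are FPKM, fragments normalised to transcript length and sequencing depth. A gene is called higher or lower where the log2 ratio of knockout over wild type, each with 1 FPKM added, was at least 1 in size. Folds are ratios of scaled fragment counts with 95% Clopper-Pearson intervals, which cover counting error only. Where the fragments of a gene are given as a pair, the wild-type library comes first, and a bare value beside a gene is its log2 ratio. MMP9, CD3D, CD79A and PTCRA lie outside the rule for named genes and were chosen after their values were seen.

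RAG2 (chromosome 2, 24547605 to 24553944 in Sscrofa11.1) remained transcribed in the knockout thymus. It stood at 606 FPKM in the wild-type and 1072 FPKM in the knockout library, a 1.77-fold difference (interval 1.69 to 1.86) with a log2 ratio of 0.82, under the size needed for a call. RAG1, listed as RAG-1 (chromosome 2, 24565447 to 24573853), was 2.08-fold higher in the knockout thymus (2.05 to 2.11), at 3435 and 7134 FPKM. In lymph node RAG-1 was also higher in the knockout, at 1.27 and 10.1 FPKM (11 and 91 fragments), and in spleen it was lower, at 2.14 and 0.0963 FPKM (19 and 1 fragments). RAG2 in lymph node had 0 and 5 fragments, and its log2 ratio of 1.11 meets the size threshold with a counting interval that includes equal levels. In spleen it had 4 and 0 fragments, under the expression minimum. A transcript level does not show whether the protein works, so these values do not check the genotype labels.

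**Figure D1:**
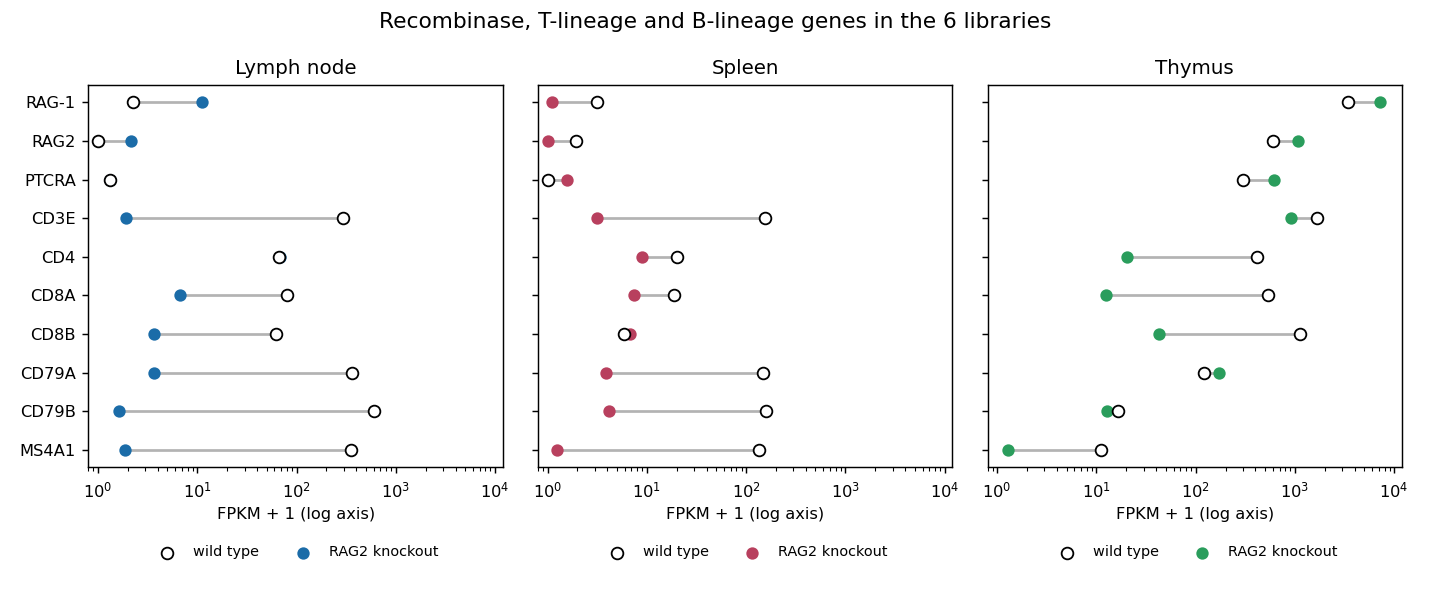
FPKM plus 1 on a log axis for 10 recombinase, T-lineage and B-lineage genes, with 1 panel per tissue, open circles for the wild-type library, filled circles for the RAG2 knockout library and a line joining the pair. The B-cell gene MS4A1 lies lower in the knockout in each panel, CD4 lies at nearly the same level in both lymph node libraries, and RAG-1, RAG2 and PTCRA lie higher in the knockout thymus.

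The lymph node comparison concerns a peripheral lymphoid organ in the RAG2 knockout. B-cell and T-cell genes were lower, with the lowest medians of all lists. All 8 measured members of the B-cell list were lower (median log2 ratio -6.59). Among them were the receptor signalling chain CD79B (988-fold lower, 273 to 8167, from 1891 to 2 fragments) and the surface protein MS4A1 (400.0-fold lower, 184 to 1091). Of 20 measured T-cell genes 19 were lower (median -3.45), including the CD3 chains CD3E (313-fold lower, 107 to 1518) and CD3G (58.5-fold lower) and the transcription factor BCL11B (51.9-fold lower). The exception was CD4, at 65.2 FPKM in wild type and 67.1 FPKM in the knockout. Genes of dividing cells were lower in 9 of 11 cases (median -2.26), led by the mitotic kinase CDK1 (-3.47), topoisomerase TOPOII (-3.20) and CDC20 (-2.75).

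Fat-cell genes were higher in the knockout lymph node. Of 18 measured members of the adipocyte list 16 were higher (median 3.48). The hormone adiponectin, ADIPOQ, was 256-fold higher (159.7 to 439.9), the lipid droplet coat protein PLIN1 102-fold higher (62.6 to 179) and the gluconeogenic enzyme PCK1 at least 188-fold higher, with 0 against 591 fragments. The neutrophil list had 4 of 7 members higher and 1 lower, MMP9 (median 4.91). RETN was at least 21.7-fold higher, and the antimicrobial calcium-binding proteins S100A12 and S100A9 were 50.7-fold and 52.6-fold higher, from 2 and 3 fragments in wild type (intervals 13.7 to 424 and 17.7 to 258). The red-cell gene HBB, a marker of blood in the sample, was 18.3-fold higher in the same library. Among natural killer cell genes 3 of 13 were higher and none lower (median 0.42). The antimicrobial NK-lysin NKL was 23.3-fold higher (13.1 to 45.6), with CCL5 at 1.28 and NKG7 at 1.17. Macrophage genes were higher in 7 of 21 cases and lower in 1 (median 0.68), with the complement receptor VSIG4 at 2.54 and FCGR1A at 0 and 10 fragments.

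Matrix, vessel and smooth muscle genes were also higher in part, in the same library as the fat-cell genes and HBB. The fibroblast and collagen list had 5 of 13 members higher and 1 lower (median 0.81), with DCN at 2.72, MFAP5 at 2.71 and the collagen cross-linking enzyme LOX at 2.15. Blood endothelial genes were higher in 3 of 9 cases (median 0.91; CLDN5 1.44, NOS3 1.095, DARC 1.099). Smooth muscle genes were higher in 5 of 9 cases (median 1.13; SMTN 2.01, PLN 1.61, TAGLN 1.48). Of the lymphatic and stromal list 3 members were higher (IL15 1.796, PROX1 1.31, LTBR 1.13) and 3 of 11 lower (median -0.0857). Complement and acute-phase genes were higher in 8 of 15 cases and lower in 1 (median 1.08), with the copper carrier CP at 5.18 (3 and 491 fragments), haptoglobin HP at 3.05 and the complement inhibitor CD55 at -2.11. Inflammatory cytokine genes were higher in 9 of 22 cases and lower in 1 (median 0.43; PTX3 3.95, IL8 2.33). Interferon-response genes were higher in 7 of 21 cases (median 0.51; OAS1 1.95, IFIT1 1.71).

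The innate lymphoid list had 3 of 8 members higher and 2 lower (median 0.31), with the receptor IL23RA at 2.46 and the lymphotoxins LTB and LTA at -3.10 and -1.77. The germinal centre list was lower in 3 of 4 cases (median -1.76; GCET2 -2.89, EZH2 -1.68). The plasma cell list was lower in 3 of 8 cases (median -0.0479), with the B-cell coactivator POU2AF1 at least 84.0-fold lower and CD38 at -2.13. Of the rearranging-thymocyte list 3 members were higher, among them RAG2 on 0 and 5 fragments, and 3 of 8 lower (median -0.26; CD8B -4.10, LEF1 -3.84). Of the early T-lineage list 2 were higher and 2 of 10 lower (median -0.17; BCL11A -2.66, NFE2 2.44 from 1 to 26 fragments, KIT 1.17). The recombination and end-joining list had 2 of 7 higher, RAG-1 and RAG2, and 1 lower (median -0.43; HMGB2 -1.76). The heat-shock and immediate-early list had 4 lower and 2 higher of 12 (median -0.42; FOS 2.82, HSPH1 -2.05, DNAJB1 -1.66). The erythroid list had 2 of 6 higher and 1 lower (median 0.46; HBB 4.16, the iron receptor TFRC -1.08). The lymphocyte growth cytokine list had 3 higher and 2 of 12 lower (median 0.00583). The type 2 and type 17 list had 2 higher and 1 of 6 lower (median -0.24; CXCR6 2.40, IL13 with 2 and 10 fragments), and its median turned to 1.57 with a minimum of 5 FPKM or of 10 fragments, the latter chosen after seeing the data. With 10 fragments the growth cytokine and skeletal muscle medians turned to -0.0693 and 0.0612. A pseudocount of 5 brought the germinal centre and complement medians to -0.997 and 0.714. Without an expression minimum, which adds genes near 0, the neutrophil, interferon-response, innate lymphoid and progenitor medians were 2.54, 0.331, 0.136 and 0.0876. Medians of the lists with fewer than 3 called members were -0.32 for dendritic cell, 0.27 for mast cell and eosinophil, 1.01 for platelet (0.172 without an expression minimum), and 0.92 for thymic epithelium (2.18 with a minimum of 5 FPKM). They were -0.85 for skeletal muscle, -0.74 for MHC class II, -0.26 for MHC class I and -0.38 for p53 and apoptosis genes, and 0.49 for haematopoietic progenitor, -0.72 for ribosomal protein, -1.07 for histone and 0.51 for keratin genes.

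In all, 446 of 2910 measured genes were higher and 299 lower in the knockout lymph node, and 382 and 258 of these also had a counting interval that excluded equal levels. With a pseudocount of 5 the higher and lower genes numbered 299 and 211. By the counting interval 5 interferon-response genes and 2 growth cytokine genes were higher, 2 germinal centre and 2 plasma cell genes were lower, and the inflammatory cytokine, type 2 and type 17, and skeletal muscle lists had 0 lower. The extremes of all genes were, besides genes named above, the zinc-binding metallothionein MT1A (at least 29.3-fold higher), TUSC5 (at least 58.0-fold higher), SMAF1 (at least 9.89-fold higher) and DAPL1 (at least 59.9-fold lower). Genes that the rule named but that rested on fewer than 10 fragments in both libraries get no fold: NCOA3 (1 and 0), ST7 (2 and 0), IL21 (2 and 0), IRF4 (2 and 1), GPNMB (0 and 4) and HBE1 (0 and 6). The others were CXCL11 (0 and 5), CCL3L1 (0 and 6), CSF2 (0 and 6) and IL2 (0 and 2). With genes at 0 in a library placed at their bound, the medians were -3.25 for T cell, -6.52 for B cell, -1.19 for germinal centre, 0.60 for macrophage, 4.44 for neutrophil and 3.45 for adipocyte genes. They were 0.94 for complement genes, 0.49 for thymic epithelium, 0.0 for skeletal muscle, -0.0347 for growth cytokine and -0.0286 for type 2 and type 17 genes.

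In spleen, the blood-filtering lymphoid organ, most B-cell and T-cell genes were again lower. The B-cell list was lower in 6 of 8 cases (median -5.24). MS4A1 was 523-fold lower (144 to 4327, from 896 to 2 fragments) and POU2AF1 at least 46.7-fold lower. Of 19 measured T-cell genes 12 were lower (median -1.16, or -0.909 with a pseudocount of 5), with CD3E 71.4-fold lower (35.9 to 166), the helper-cell ligand CD40LG at least 6.23-fold lower and LEF1 13.5-fold lower. The T-cell genes differed among themselves: CD3D stood at 83.7 FPKM in wild type and 92.9 FPKM in the knockout, and CD3G at 81.6 and 52.9 FPKM, short of a call. Among natural killer and cytotoxicity genes 6 of 14 were higher and 2 lower (median 0.73), with NKL 10.7-fold higher (8.53 to 13.6), granzyme GZMB at least 3.43-fold higher and GZMK at -1.80.

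Neutrophil and interferon-response genes were higher in the knockout spleen. All 8 measured neutrophil genes were higher (median 3.82), with S100A9 99.2-fold (47.9 to 248), S100A12 40.0-fold (19.2 to 100.3) and S100A8 38.5-fold (21.8 to 74.9) higher, while the red-cell gene HBB was 2.12-fold lower (2.09 to 2.16). Interferon-response genes were higher in 15 of 21 cases and lower in none (median 1.69). Among them were the chemokines CXCL11 (23.1-fold, 3.81 to 947, from 1 to 27 fragments) and CXCL9 (12.8-fold, 9.49 to 17.8) and the antiviral tether BST2 (9.13-fold, 2.86 to 46.6, from 3 to 32 fragments). MHC class I genes were higher in 4 of 14 cases (median 0.60; B2M 1.38, PSME2 1.20, SLA-2 1.09). Macrophage genes split, with 6 of 20 higher and 4 lower (median -0.11). The sialic acid receptor SIGLEC-1 and the scavenger receptor MSR1 were 16.01-fold and 7.06-fold lower, and VSIG4 was 7.71-fold higher. Fibroblast and collagen genes were lower in 8 of 13 cases (median -1.14; THY1 -2.92), and 1 member was higher, the protease inhibitor TIMP1, at 14.4-fold (11.8 to 17.7). The chemokine CCL19, which draws T cells and dendritic cells, was 20.6-fold higher (15.03 to 29.0), and the T-cell survival factor IL7 was lower at -2.45 in the same list of lymphatic and stromal genes (TNFSF13B 1.61). That list had 3 of 11 members higher and 2 lower (median 0.0756).

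Platelet genes were higher in 6 of 7 cases in spleen (median 1.39; NFE2 2.12, ITGB3 1.89, TREML1 1.85). The erythroid list had the transcription factors KLF1 (2.22) and GATA1 (2.17) higher and HBB (-1.13) lower (7 measured, median 0.34). Complement genes went both ways, 3 higher and 3 of 15 lower (median 0.17; C3 2.30, CP 1.68, TF -2.65). Inflammatory cytokines had 6 higher and 1 of 20 lower (median 0.23), with IL8 at least 8.85-fold higher, CCL3L1 at 2.66 (2 and 18 fragments) and TREM1 at 1.74 (3 and 19 fragments). The heat-shock and immediate-early list was lower in 4 of 12 cases (median -0.23; DNAJB1 -2.67, HSPH1 -2.60, DNAJA1 -1.58). The innate lymphoid list was lower in 3 of 6 cases (median -1.01, or -0.445 with a pseudocount of 5; LTB -2.86, LTA at least 4.28-fold lower, KIT -1.54). The early T-lineage list had 3 lower and 1 of 10 higher (median -0.68; IL7R -2.67, NFE2 2.12), and the rearranging-thymocyte list had 4 of 7 lower (median -1.18; RAG-1 -1.52, CCR9 -1.33, LEF1 -3.22), with a median that turned to 0.212 with a minimum of 5 FPKM. The growth cytokine list had 3 higher and 3 of 11 lower (median 0.61; JAK1 2.23 from 2 to 13 fragments). The type 2 and type 17 list had 2 of 4 each way (median 0.32; CXCR6 1.996, IFNG 1.70 from 2 to 12 fragments, GATA3 -1.26). The dendritic cell list had 2 of 7 higher (median 0.48; FSCN1 1.56) and 2 lower, CCL17 and CCL22, each on 2 and 0 fragments. The adipocyte list had 2 of 15 each way (median -0.0905; AQP7 1.34). The thymic epithelium list had 1 higher and 3 of 6 lower (median -0.99; DLL4 -1.34). Medians of the remaining lists were -0.42 for germinal centre, -0.31 for plasma cell, -0.28 for recombination and end joining, -0.81 for mast cell and eosinophil, and 0.26 for blood endothelial cell genes. They were 0.44 for skeletal muscle, -0.46 for smooth muscle, 0.0202 for MHC class II and -0.19 for cell cycle genes. They were -0.20 for p53 and apoptosis, 0.17 for haematopoietic progenitor, -0.46 for ribosomal protein, -0.0993 for histone and -0.67 for keratin genes. The MHC class II median turned to -0.019 with counts scaled to their total, the skeletal muscle median to -0.22 with a minimum of 5 FPKM and the adipocyte median to 0.529 with a minimum of 10 fragments.

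Of 2849 genes measured in spleen, 253 were higher and 286 lower, and 213 and 240 of them had an interval that excluded equal levels. With a pseudocount of 5 they numbered 166 and 160. By the counting interval the thymic epithelium list had 0 higher and 1 lower, the dendritic cell list 2 and 0, the adipocyte list 2 and 1, the type 2 and type 17 list 2 and 1, and the growth cytokine list 3 and 2. The B-cell median was -3.44 with a pseudocount of 5 and the type 2 and type 17 median 1.85 with a minimum of 5 FPKM, and without a minimum the natural killer, thymic epithelium and growth cytokine medians were 0.331, -0.318 and 0.0. BCKDHB was the highest by FPKM (log2 ratio 7.27), but its fragments, 66 and 76, gave a ratio of 0.986 (0.70 to 1.39), so the call rests on the FPKM calculation alone. Genes named by the rule on fewer than 10 fragments in both libraries were OCT2 (1 and 0), PID1 (3 and 0), PRKAA2 (1 and 0), NOD1 (0 and 4), PPP2CA (0 and 1), CCL17 (2 and 0) and CCL22 (2 and 0). The others were MFAP5 (3 and 0), CD70 (4 and 0), CLDN3 (4 and 1), CIDEC (8 and 1) and DGAT2 (1 and 0). With genes at 0 placed at their bound, medians were -1.05 for fibroblast, -0.65 for thymic epithelium, 0.0 for adipocyte, 0.19 for skeletal muscle, 0.0932 for inflammatory cytokine, 0.45 for MHC class I and 0.85 for type 2 and type 17 genes.

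The thymus comparison asks how far T-cell development proceeds. The coreceptors that thymocytes gain after rearranging their receptor beta chain were lower: CD8A was 47.0-fold lower (37.1 to 60.3), CD8B 27.1-fold lower (23.3 to 31.6), and CD4 21.2-fold lower (18.0 to 25.03). The homing receptor CCR9 was 51.1-fold lower (35.9 to 75.5). RAG-1 as given above, the pre-T-cell receptor chain PTCRA (2.02-fold, 1.87 to 2.19) and the interleukin-7 receptor IL7R (2.37-fold, 2.22 to 2.53) were higher, GATA3 was lower (-1.09, or -0.98 with counts scaled to their total), and RAG2 and KIT (0.70) did not reach a call. Of the recombination and end-joining list 1 of 7 members was higher, RAG-1. T-cell genes as a group were lower in 15 of 20 cases (median -1.97), with the costimulatory receptor CD28 at 99 and 1 fragments, whereas CD3E (log2 ratio -0.88), CD3G (-0.26), LEF1 (-0.38) and BCL11B (0.20) did not reach a call. The rearranging-thymocyte list had 2 members higher and 4 of 9 lower (median -0.38), and the early T-lineage list 4 higher and 1 of 10 lower (median 0.65; NFE2 2.40, HHEX 1.58). NFE2 is also on the platelet list and was higher in lymph node (2.44) and spleen (2.12) as well.

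Neutrophil and macrophage genes were mostly higher in the knockout thymus, and dendritic cell genes went both ways. Neutrophil genes were higher in 7 of 8 cases (median 4.22), with lactoferrin LTF 273-fold higher (75.2 to 2259, from 2 to 559 fragments), RETN at least 19.9-fold and S100A8 26.9-fold higher (17.2 to 44.3), and HBB was 5.24-fold higher (4.88 to 5.64) in the same library. Macrophage genes were higher in 17 of 21 cases and lower in 1 (median 1.5; FCN1 3.84, LYZ 2.78). Dendritic cell genes were lower in 4 of 7 cases and higher in 2 (median -2.43). The chemokine CCL22 was at least 13.7-fold lower, CCL17 27.7-fold lower (4.56 to 1132, from 27 to 1 fragments) and the tryptophan-degrading enzyme IDO1 at least 15.7-fold lower. The higher members were XCR1 (2.12) and IRF8 (1.48), named after their values were seen. Among natural killer genes 6 of 13 were higher and 3 lower (median 0.88; NKL 3.61 from 2 to 36 fragments, FCER1G 2.18, XCL1 -1.92). B-cell genes were lower in 5 of 8 cases (median -1.19, or -0.758 with a pseudocount of 5 and -0.922 with a minimum of 5 FPKM), with MS4A1 at 68 and 2 fragments. CD79A and CD79B stood at log2 ratios of 0.52 and -0.39.

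Most fat and vessel genes were higher in the knockout thymus as well. The adipocyte list had 12 of 17 members higher and 1 lower (median 1.36, or 0.919 with a pseudocount of 5). ADIPOQ was 10.6-fold higher (8.46 to 13.5), PLIN1 7.41-fold higher and PCK1 at 3.62, from 1 to 98 fragments. Of blood endothelial genes 6 of 9 were higher (median 1.29; CLDN5 2.27, DARC 2.17, NOS3 1.99). Of the lymphatic and stromal list 4 were higher and 2 of 11 lower (median 0.35; CCL19 -2.82, LTBR 1.68, ICAM-1 1.26). The thymic epithelium list had 2 lower and 1 of 8 higher (median -0.59), and the epithelial chemokine CCL25 that draws progenitors, the ligand of CCR9, was 3.43-fold lower (3.04 to 3.88). Collagen gene COL5A2 was 10.5-fold lower (9.97 to 11.05) in a fibroblast list that had 3 lower and 2 of 13 higher (median -0.50; DCN 1.40, TIMP1 1.46). Skeletal muscle genes, which thymic medullary cells also express, were lower in 6 of 12 cases and higher in 1 (median -0.995), with the light chain MYLPF at least 8.54-fold lower, TNNC1 at -2.85 and TNNI1 at -2.43. Complement and acute-phase genes were higher in 7 of 13 cases (median 1.07), led by HP at 19.7-fold (17 to 23.0).

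The heat-shock and immediate-early list was lower in 5 of 12 cases in the knockout thymus (median -0.69), among them the chaperones HSPA8, 7.04-fold lower (6.79 to 7.30), HSPH1 at -2.66 and DNAJA1 at -1.84. Histone genes were lower in 3 of 4 cases (median -1.16; H2AFZ -1.27, HIST1H3E -1.18, HIST1H2BD -1.15), and cell-cycle genes in 1 of 11 (median -0.55). Inflammatory cytokines had 7 lower and 5 of 22 higher (median -0.44), with CCL20 at least 6.83-fold lower, PTX3 at 4.13 and TREM1 at 0 and 10 fragments. Interferon-response genes had 7 higher and 1 of 22 lower (median 0.36; OAS1 2.11). The innate lymphoid list was lower in 4 of 8 cases (median -1.04, or -0.235 with a minimum of 5 FPKM; LTB -3.73, IL23RA -1.83), and the plasma cell list in 3 of 8 (median -0.19; POU2AF1 -1.80, CD38 -1.67). The type 2 and type 17 list was lower in 4 of 6 cases, 1 of them with an interval that excluded equal levels, and higher in 1 (median -1.12; CXCR6 1.57). Its median turned to 0.243 with a minimum of 5 FPKM or of 10 fragments. The erythroid list had 2 higher and 1 of 7 lower (median 0.44). The growth cytokine list had 3 higher and 1 of 12 lower (median 0.0601; KITLG with 4 and 10 fragments). Medians of the remaining lists were -1.03 for germinal centre, 0.0494 for recombination and end joining, 0.26 for mast cell and eosinophil, 0.11 for platelet, and 0.14 for smooth muscle genes. They were 0.52 for MHC class II, -0.14 for MHC class I, -0.11 for p53 and apoptosis, 0.57 for haematopoietic progenitor, -0.12 for ribosomal protein and -0.75 for keratin genes. The p53 median turned to 0.00811 with counts scaled to their total and the growth cytokine median to -0.00649 with a minimum of 10 fragments, and the germinal centre median was -0.58 with a pseudocount of 5.

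Of 2908 genes measured in thymus, 441 were higher and 317 lower, and 392 and 248 had an interval that excluded equal levels. With a pseudocount of 5 they numbered 272 and 183. By the counting interval the inflammatory cytokine list had 4 higher and 4 lower, the growth cytokine list 1 and 0, the erythroid list 2 and 0, the interferon-response list 5 and 1, the thymic epithelium list 1 and 1, the complement list 5 higher, and the innate lymphoid and plasma cell lists 3 and 2 lower. With a minimum of 5 FPKM the platelet, skeletal muscle and keratin medians were 2.39, -2.20 and -1.96, and without a minimum the natural killer, dendritic cell and skeletal muscle medians were 0.413, -1.21 and -0.0547. Besides genes given above, the extremes were the scavenger receptor CD163L1 (at least 91.2-fold lower), the metabolic kinase PDK4 (86.1-fold higher, 62.1 to 123), ESR1 (log2 ratio 7.57 on 5 and 19 fragments, a count ratio of 3.71) and EIF1AY. Genes named by the rule on fewer than 10 fragments in both libraries were 0610007P14RIK (2 and 0), MALL (2 and 0), IRF4 (2 and 0), GPNMB (0 and 4), BST2 (0 and 2), FCER2 (8 and 0) and IL-5 (3 and 0). The others were HBE1 (2 and 0), KLF1 (0 and 7), CLDN3 (5 and 0), CXCL11 (1 and 7), C5 (0 and 1), ITIH4 (0 and 3), IL2 (3 and 0) and IL21 (1 and 0). With genes at 0 placed at their bound, medians were -1.54 for T cell, -0.71 for germinal centre, -0.16 for plasma cell, -0.43 for innate lymphoid, and 1.31 for macrophage genes. They were 0.27 for interferon response, -0.15 for inflammatory cytokine, 0.83 for complement, -0.00324 for growth cytokine and -0.0174 for type 2 and type 17 genes.

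**Figure D2:**
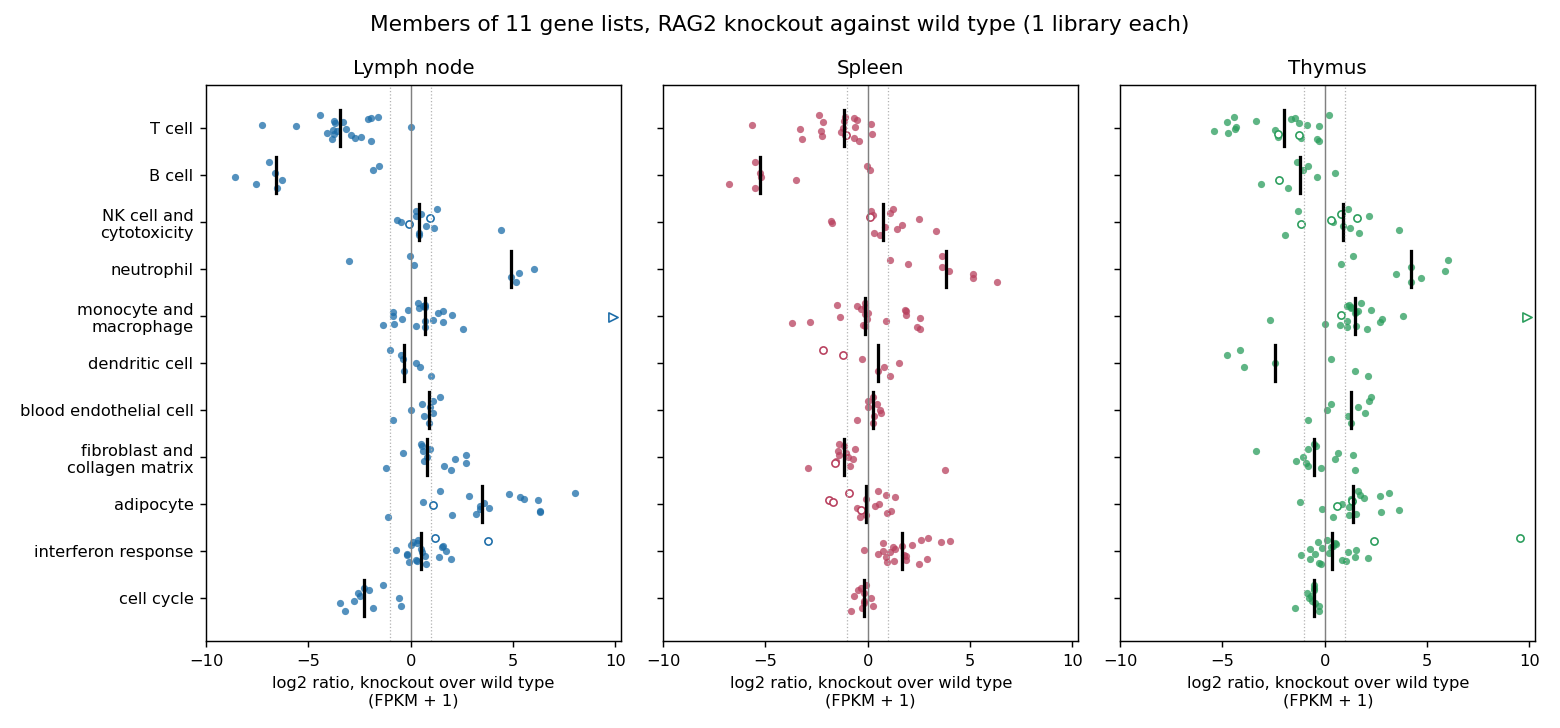
Log2 ratios of knockout over wild type (FPKM plus 1) for the measured members of 11 gene lists, with 1 panel per tissue, 1 point per gene, open points for genes under 10 fragments in both libraries, a triangle for a gene beyond the axis, black bars for list medians and dotted lines at the size threshold. B-cell and T-cell members lie mostly to the left and neutrophil members mostly to the right in each panel.

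Part of the differences were shared by the tissues. Genes higher in all 3 tissues numbered 51 of 2671 measured in all, where independent lists would give 3.90. Genes lower in all 3 numbered 38, against 1.87. With a pseudocount of 5 the counts were 30 and 14, and with a minimum of 5 FPKM the lower genes numbered 21. The shared higher genes include the neutrophil proteins S100A8, S100A9 and S100A12, NKL, NKG7, CCL5, the chemokine receptor CXCR6, VSIG4, PCK1 and the interferon-induced enzyme OAS1. The shared lower genes include MS4A1, POU2AF1, CD8A, CD28, CD40LG, LTA, LTB, DAPL1 and the chaperones HSPA8 and HSPH1. The labels do not say whether the tissues came from the same animals, so the excess over independence need not come from the genotype. The 18S ribosomal RNA gene RN18S, named after its values were seen, is also among the shared higher genes (1.90, 1.33 and 1.61 in lymph node, spleen and thymus). EIF1AY, on the Y chromosome (9687350 to 9704489), had 209, 194 and 597 fragments in the knockout lymph node, spleen and thymus and 0, 0 and 1 in wild type. A Y chromosome in the knockout samples and none in the wild-type ones would give this pattern, but the labels give no sex. Sex and genotype would then coincide, so any gene's difference between the groups may be one of sex. Across genes, which are not independent replicates, Pearson's correlation of the log2 ratios was 0.519 between lymph node and thymus, 0.378 between lymph node and spleen and 0.213 between spleen and thymus. By ranks, Spearman's correlation of the same ratios was lower, at 0.488, 0.253 and 0.122. Genes called in opposite directions numbered 60 between lymph node and spleen, 43 between lymph node and thymus and 73 between spleen and thymus, or 43, 24 and 48 where both counting intervals excluded equal levels. The number that independent lists would give was not calculated for these, so no excess of opposite genes is shown. Spearman's correlation of expression between knockout and wild type was 0.879 in lymph node, 0.930 in spleen and 0.925 in thymus, and that between the wild-type lymph node and spleen was 0.900.

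Each list's median was placed among 10000 random lists matched on mean expression, as a description of these libraries. In lymph node the T-cell, B-cell and cell-cycle medians lay at percentile 0.0 and the neutrophil, macrophage, fibroblast and adipocyte medians at percentile 100. In spleen the T-cell, B-cell and fibroblast medians lay at 0.0 and the neutrophil, interferon-response and natural killer medians at 100. In thymus the T-cell median lay at 0.0, the B-cell median at 0.36, the dendritic cell median at 0.04 and the heat-shock and immediate-early median at 0.09. The neutrophil, macrophage and adipocyte medians lay at 100 there. The ribosomal protein median lay at 0.015 in lymph node and 0.03 in spleen, though only 2 and 1 of its 41 members were lower, and at 96.5 in thymus, where its median was -0.12. No immunoglobulin, T cell receptor or mitochondrially encoded gene is listed under such a symbol, and none of the 234 small RNA genes listed reached the expression minimum.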

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

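All tests in this part were chosen after the results were seen, except that of the X-linked genes, whose prediction was written before its values were looked up.

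Among the named genes, 14 were called higher in 1 tissue and lower in another, each with a counting interval that excluded equal levels, in 21 pairs of tissues. With 1 library per group none of these differences between tissues was tested, and their number was not held against that of independent lists. Differences are given as the log2 ratio in the tissue named first minus that in the other. Between spleen and thymus they were 7.08 for the chemokine CCL19, 3.98 for the actin bundler FSCN1, -3.91 for IL7R and -5.21 for the lectin FCN1. Between lymph node and spleen the difference was 2.71 for the growth factor receptor KIT and -2.71 for the B-cell survival factor TNFSF13B, and between lymph node and thymus it was 4.29 for IL23RA. RAG-1 differed by 3.80 between lymph node and spleen and by -2.57 between spleen and thymus. The corresponding values were 4.39 and -5.51 for the scavenger receptor MSR1, 4.11 and -2.80 for the matrix proteoglycan DCN, 2.23 and -2.46 for the smooth muscle gene CNN1, 7.40 and -3.14 for the lipid droplet gene CIDEC, -3.92 and 2.25 for the germinal centre gene GCET2, and 5.29 and -3.52 for HBB. CIDEC in spleen rests on 8 and 1 fragments, GCET2 in spleen on 3 and 13, and RAG-1 in spleen on 19 and 1.

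Fat-cell genes were higher in the knockout lymph node (median 3.48). A loss of lymphocytes that raised every other cell type alike would move the adipocyte and blood endothelial medians by the same amount. The adipocyte median exceeded the blood endothelial median by 2.57 (bootstrap interval over members 1.70 to 4.62). Both medians were known when the lists were chosen, and the interval covers the spread among list members, not that between animals. In these libraries the lists did not rise alike, so an equal rise alone does not describe them. A share of the rise from such a loss stays open. Fat around the node, taken at dissection, and fat cells within it cannot be told apart: that 16 of 18 members were higher is the pattern itself and tests neither. A higher amount of fat tissue as an effect of the genotype was not tested separately and stays open.

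Neutrophil genes were mostly higher in each knockout tissue; in spleen, more blood in the knockout sample is argued against by HBB, which was lower (log2 ratio -1.13), although spleen also holds red cells of its own. In lymph node and thymus blood stays open, with HBB higher by 4.16 and 2.39: the lower quartile of the neutrophil genes it was held against is near 0 in lymph node (0.0656), so almost any rise would pass, and in thymus HBB fell short of it (2.95). A loss of lymphocytes that raised every other cell type alike is argued against as the only cause for these genes in spleen and, weakly, in thymus. There the neutrophil median exceeded the macrophage median by 3.92 (1.99 to 5.31) and 2.72 (0.101 to 4.23). The intervals cover the spread among list members with 1 library per group, not that between animals, and the thymus bound lies near 0. In spleen the macrophage list is an unsteady reference, with 6 of 20 members higher and 4 lower. All these medians were known beforehand. In lymph node the interval for the neutrophil genes held 0 (4.22, -0.933 to 5.03), so this comparison decides nothing for them. Fat-cell and vessel genes did not rise alike there, as given above, on medians that were also known beforehand. An equal rise of every other cell type alone therefore does not describe that library. An effect of the genotype and an infection of these animals both stay open, as untested.

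EIF1AY was present in the 3 knockout libraries and nearly absent in wild type. Fragments of its X-linked copy EIF1AX, counted under the wrong name, are argued against: no wild-type library had more than 1 fragment of EIF1AY, beside 1655, 1785 and 2484 fragments of EIF1AX. Male knockout and female wild-type animals would give this pattern of EIF1AY. KDM5C, TRAPPC2 and SYAP1, which escape X inactivation in other mammals, had medians below 0 in all tissues as predicted, the highest at -0.0499. These medians decide nothing, since those in lymph node and thymus are values of TRAPPC2, within counting error. In lymph node, spleen and thymus KDM5C stood at -0.36, -0.19 and -0.26, each beyond counting error, TRAPPC2 at -0.0499, -0.0759 and -0.0978, each within it, and SYAP1 at 0.0128, -0.17 and 0.31, beyond it in spleen and thymus in opposite directions. EIF1AX, outside the prediction, had count folds of knockout over wild type of 0.940 (0.877 to 1.007) in lymph node. They were 0.807 (0.7545 to 0.863) in spleen and 0.881 (0.831 to 0.933) in thymus, lower beyond counting error in these 2 tissues. With 1 library per group these folds do not settle the sex. The gene SRY, on the Y chromosome like EIF1AY, had 0 fragments in every library and so does not separate the groups. EIF1AY separates the groups in all 3 tissues, so a difference in sex would coincide with genotype in every comparison. Sex and genotype therefore cannot be told apart in these libraries, which hold 1 library per group and tissue, and the labels give no sex.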

How the results depend on the processing

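The interval for comparisons between tissues and the minimum of 10 fragments were chosen after seeing the data, and causes were not tested except where named. List medians and named genes' values were followed under the scalings, pseudocounts, expression minimums and centring. Of the medians, 889 stayed on their side of the threshold without changing sign, some of them falling to 0. Another 8 under the threshold changed sign, 42 became weaker, 26 stronger and 5 reversed. Of the named genes' values, 3824 stayed on their side without changing sign, 5 under the threshold changed sign, 166 became weaker, 20 stronger and 3 reversed. An expression minimum only drops a gene and leaves its value as it is. The 462 values without a minimum, 395 with 5 FPKM and 389 with 10 fragments therefore counted as unchanged by construction. A pseudocount cannot change a gene's sign, so only the scalings and centring could do so. Under the scalings, centring, FPKM minimums and counting interval planned, the counts of higher and lower genes lay between 363 and 450 and between 249 and 299 in lymph node, 213 and 260 and 213 and 294 in spleen, and 370 and 486 and 219 and 317 in thymus. A threshold of 2 by its construction left 163 higher and 112 lower genes in lymph node, 79 and 76 in spleen and 110 and 105 in thymus. A pseudocount of 5, which shrinks weakly expressed genes, left 299 higher and 211 lower genes in lymph node. It left 166 higher and 160 lower genes in spleen, 272 and 183 in thymus, and 30 higher and 14 lower in all tissues. It brought the medians of T-cell genes in spleen to -0.909, B-cell genes in thymus to -0.758 and adipocyte genes in thymus to 0.919. A pseudocount of 0.1 gave 480 higher and 331 lower genes in lymph node, 284 and 331 in spleen, 488 and 346 in thymus. With it the natural killer median in thymus was 1.14. A minimum of 5 FPKM tests fewer genes: 21 were lower in all tissues, the B-cell median in thymus was -0.922, the natural killer median there 1.12, and the rearranging-thymocyte median in spleen reversed to 0.212. Under it and under a minimum of 10 fragments, the type 2 and type 17 median reversed to 1.57 in lymph node and 0.243 in thymus, and under the latter the natural killer median in thymus was 1.12 as well and the adipocyte median in spleen 0.529. BCKDHB in spleen reversed to -0.065, -0.0225 and -0.0159 with counts scaled by total, TMM and DESeq2, because its count ratio lies near 1. Genes opposite between tissues numbered 24 for lymph node and thymus and 48 for spleen and thymus with the counting interval. Spearman's correlations of knockout with wild type were 0.9097, 0.949 and 0.9414 in lymph node, spleen and thymus for counts. Scaling by 1 factor per library leaves ranks as they are, so all the scalings give these same values by construction. By FPKM the correlations were 0.9316, 0.9563 and 0.9476 without a minimum, and 0.8482, 0.9142 and 0.9121 with a minimum of 5 FPKM. Scaling to the total moved the median of all thymus genes by 0.116. A fit of the genotype across tissues, paired within tissue, was not made. Depth limits the calls on fewer than 10 fragments, which numbered 117, 91 and 146 in lymph node, spleen and thymus.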

Other observations

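The genes in this part were chosen after their values were seen, and no test of an explanation was made for them. Of 3 antimicrobial peptides of pig neutrophil granules, PMAP-36 had 0 and 11 fragments in wild-type and knockout lymph node, was 8.09-fold higher in spleen (4.07 to 18.3) and 46.3-fold higher in thymus (25.7 to 93.4), PR39 had 0 and 6, 2 and 16, and 2 and 108 fragments in lymph node, spleen and thymus, and NPG4 had 0 and 2, 3 and 42, and 23 and 275. The lectin FCN2 was 3.01-fold higher in lymph node, 13.6-fold in spleen and 93.7-fold in thymus (from 3 to 288 fragments, 31.8 to 457). The macrophage survival factor CD5L was 3.01-fold, 3.63-fold and 3.15-fold higher. The secreted phospholipase PLA2G2D was 19.8-fold higher in spleen (15.9 to 24.8) and lower in lymph node and thymus (log2 ratios -1.22 and -2.27).

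In lymph node PDK4, which turns cells from glucose to fat use, was 27.9-fold higher (25.4 to 30.8), carbonic anhydrase CA4 122-fold (from 2 to 255 fragments, 33.4 to 1013) and the uncoupling protein UCP3 93.8-fold (from 1 to 98 fragments, 16.4 to 3740). In thymus, the lipid-presenting molecules PCD1E and CD1.1 of cortical thymocytes had log2 ratios of -2.06 and -0.93, and the transporter ABCB1 was 42.1-fold lower (32.5 to 55.5), with 0.33 in lymph node and -0.0129 in spleen. The locus LOC100152327 (chromosome 14, 48800248 to 49001525) was 4831-fold lower in spleen (4137 and 1 fragments, 867 to 190900), and 38.01-fold lower in lymph node (24.9 to 61.0).

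The chaperone HSPA8 had log2 ratios of -1.61, -1.11 and -2.81 in lymph node, spleen and thymus, and HSPH1 of -2.05, -2.60 and -2.66. SLC6A8 had log2 ratios of 4.88, -5.37 and 4.17 by FPKM, while its fragment counts gave folds (not log2) of 3.63, 0.337 and 1.65 of knockout over wild type. CDH13 in spleen had a log2 ratio of 3.35 by FPKM on 94 and 69 fragments. Its count fold of knockout over wild type was 0.629 (0.454 to 0.867), the opposite direction, so the FPKM call is not borne out. Among genes with 10 or more fragments in both libraries, 2 in spleen differed 2-fold or more by FPKM against the direction of their counts. There were 0 in lymph node and 0 in thymus.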
